A study of Mus musculus with 9 samples.

How the data were processed

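RNA of mouse oocytes arrested at the second meiotic metaphase was measured by sequencing in 9 libraries, 1 library per mouse and 15 oocytes per library. The mice were ICR females in 3 groups of 3: untreated control, stress, and stress plus the herbal recipe Kai Yu Zhong Yu (KYZY). The stress group was exposed to a daily stressor for 6 weeks in a chronic unpredictable mild stress model. The KYZY group received the stressors for 6 weeks and then a decoction of the recipe by gavage, at 0.1 ml per day for 4 weeks. All mice were given 7.5 IU of PMSG and 7.5 IU of hCG to induce ovulation. Oocytes were taken from the oviducts 16 hours later and freed of their cumulus cells with hyaluronidase. The cDNA was made with the SMART-Seq v4 kit and cut into libraries with Tn5 transposase, a protocol without molecular identifiers and without strand information.

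The deposited tables hold expected counts, whole-number estimates of the reads per gene, not normalized and with 1 table per library. The unit was read from the values and from the tools listed by the authors, since the tables themselves name no unit. The submitters' notes name bcl2fastq 2.20, Trim Galore, HISAT2, StringTie and DESeq2 and the mouse genome builds GRCm38 and mm10, without the role or settings of each tool and with no other version. Values of 4 and 8 were more frequent than their neighbours in every library: in control 1, 401 genes had a value of 4, while 53 genes had a value of 3 and 224 had a value of 5. A single read pair therefore appeared to be worth about 4 units, so that counting noise is larger than the totals convey. The floor for a gene at 0 was set at 3 read pairs, or 12 counts, which came to 0.105 to 0.245 CPM per library (CPM is the customary unit for a gene's count relative to its TMM-scaled library total). Floors cover counting error only, because amplified reads without molecular identifiers are not independent molecules.

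Gene symbols were matched to the RefSeq annotation of GRCm38.p6, and 24076 of 24736 symbols (97.33%) had an entry there. Coordinates are given on GRCm38. The tables held 0 mitochondrially encoded genes, so the list of mitochondrial transcripts fixed for the tissue could not be tested. No pair of libraries held identical values, and no library was left out.

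Counts were analysed in R 4.3.3 with edgeR 4.0.16. Libraries were scaled by the trimmed mean of M values (TMM), and genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 13890 genes and dropped 10846. The genes kept held 99.9832% of all counts. A quasi-likelihood negative binomial model with 1 mean per group was fitted to all 9 libraries, with 6 residual degrees of freedom and robust estimation of the spread. The groups were compared by 2-sided quasi-likelihood F tests, and p values were adjusted by the Benjamini-Hochberg method over the 13890 genes, with a threshold of 0.05. Group values are means and SD of TMM-scaled CPM over 3 libraries. The common biological coefficient of variation was 0.611, and the median standard error of a log2 fold change was 0.396 in stress against control. On simulated data of the same size, in which 50 genes per fold were changed, the test recovered 2% of genes changed 2-fold, 46% of those changed 4-fold and 66% of those changed 8-fold in stress against control, with 3 false calls among 13169 genes. In the other 2 comparisons it recovered 42% of the genes changed 4-fold.

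Before the data were examined, 31 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists covered maternal-effect genes, meiosis and spindle, cohesin and chromosome segregation, egg activation, maternal mRNA translation and decay, DNA methylation and histone modification, nuclear-encoded oxidative phosphorylation, mitochondrially encoded transcripts, mitochondrial dynamics, glycolysis and the tricarboxylic acid cycle, lipid metabolism, antioxidant defence, heat shock, endoplasmic reticulum stress, apoptosis, DNA repair, autophagy and lysosome, glucocorticoid response, inflammation and interferon, PI3K, mTOR and insulin signalling, cytosolic and mitochondrial ribosomal proteins, proteasome, spliceosome, translation factors, genes of zygotic genome activation, imprinted genes, and markers of cumulus and granulosa cells, oviduct epithelium, blood and immune cells, and stroma and endothelium. Lists with at least 5 measured members were tested against all other genes with camera of limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 30 lists of a comparison, and again with the correlation estimated from the data. Members were also adjusted over the list alone. In a simulation that shifted 1 list, the test called that list and 0 of the others. The simulated genes varied independently, so this cannot show how often lists of genes that vary together are called falsely. The estimated correlation of cytosolic ribosomal proteins was 0.581 in stress against control. A list score per library is the mean of log2(CPM + 1) over the members tested.

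Named genes were to be, in each comparison, the 12 risen and 12 fallen genes with the largest change among called genes with separate groups, and up to 3 called members per list. Because fewer than 10 genes were called in each comparison, the 10 genes with the smallest p were named as not passing, and up to 2 members of highest expression were given as examples from a list. Any gene outside this rule is given as chosen after its values were seen or as called in an alternative fit.

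Replicate numbers were checked for pairing by correlating the deviations of libraries from their group means across genes. Same-numbered control and stress libraries had correlations of 0.312, 0.185 and 0.346, all above 0.1, so a fit of these 6 libraries with the replicate number as a block was added. Unlike-numbered ones had -0.407 to 0.233, and control 2 with stress 1, at 0.233, lay above the 0.185. The values therefore do not establish pairs. The mice were different animals, and the labels do not say what a shared number stands for.

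Alternatives fixed in advance were DESeq2 size factors and upper-quartile factors in edgeR, the DESeq2 1.42.0 Wald test, no filter on low counts, a filter of at least 50 counts in 3 libraries, fits of only the groups compared, a replicate block, and leaving out each library in turn. Chosen after seeing the data were counts divided by 4, leaving out the ribosomal RNA gene Rn45s, the cumulus and granulosa marker score as a covariate, leaving out the 4 libraries with the highest marker score, limma voom with a weight per library, and the block within control and stress. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The KYZY libraries have another sequencing description than the control and stress libraries, so no fit could separate a difference in sequencing from the treatment.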

Results

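Transcript levels were measured in 9 libraries of metaphase II oocytes from 9 mice, 3 control, 3 stress and 3 stress plus KYZY. Total counts were 68826061, 82214112 and 72154974 in control 1, 2 and 3, 75395961, 106990821 and 80606254 in stress 1, 2 and 3, and 74216425, 67892072 and 46324094 in KYZY 1, 2 and 3. Between 13257 and 15802 of 24736 genes had a value above 0. The ribosomal RNA gene Rn45s took 5.26% to 11.8% of counts, and the 10 most abundant genes took 17.3% to 24.5%.

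Oocyte transcripts were abundant in every group. Zbed3, a gene of the subcortical maternal complex, stood at 41750 ± 7222 CPM (SD, n = 3) in control, 47320 ± 1130 in stress and 45640 ± 6663 in KYZY oocytes. Gdf9, an oocyte-secreted growth factor, stood at 12540 ± 2791, 13530 ± 1716 and 12130 ± 3387 CPM in the same order. The Spearman correlation between libraries, computed across genes, which are not independent replicates, had a median of 0.930 within groups and 0.936 between groups. The first principal component held 46.8% of the variance and did not follow the groups. Control 3, stress 3, KYZY 2 and KYZY 3 lay at 84.8, 25.9, 96.4 and 115 on it, and the other 5 libraries lay between -91.1 and -33.6.

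The 4 libraries that stood apart also had the highest scores of cumulus and granulosa cell markers, 2.71, 2.30, 3.41 and 3.30, against 1.23 to 1.59 in the others. The 2 markers of highest expression did not separate the 4 libraries. Serpine2 was at 375, 970, 791 and 383 CPM in control 3, stress 3, KYZY 2 and KYZY 3 and at 359 to 505 in the others. Sdc1 was at 155, 381, 619 and 209 CPM against 173 to 229. Cyp11a1, Tnfaip6 and Star were chosen after their values were seen. Cyp11a1, the enzyme that starts steroid synthesis from cholesterol, reached 228 CPM in control 3, 165 in KYZY 2 and 428 in KYZY 3, 14.7 in stress 3, and 0.48 to 10.6 in the remaining libraries. Tnfaip6, a hyaluronan-binding protein of the expanded cumulus, was at 1.94, 5.14, 16.5 and 10.4 CPM in control 3, stress 3, KYZY 2 and KYZY 3 and at 0 in the other 5. Star, the cholesterol carrier of mitochondria, was at 54.9 CPM in control 3 and 76.9 in KYZY 3 but at 0.373 in stress 3 and 4.86 in KYZY 2, beside 3.54 in stress 2. The plot of the first component against the marker score shows the 9 libraries.

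**Figure D1:**
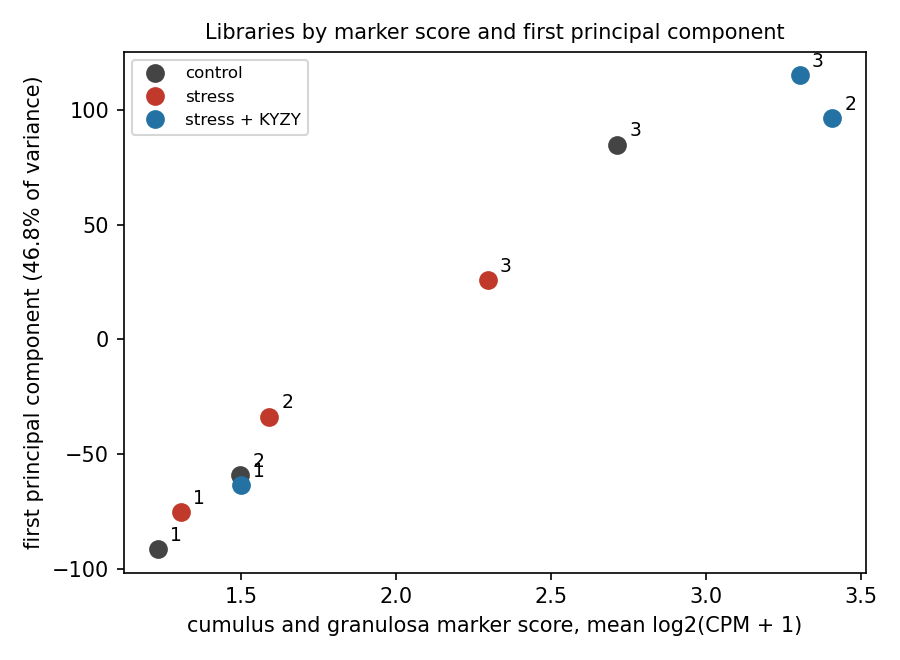
First principal component of each library against its cumulus and granulosa marker score, the mean log2(CPM + 1) of the tested markers; each point is 1 library, numbered by replicate and coloured by group. Control 3, stress 3, KYZY 2 and KYZY 3 lie at 25.9 or above on the component, and the other 5 libraries lie at -33.6 or below.

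The comparison of stress with control asked which oocyte transcripts differ after weeks of stress. The 10 genes with the smallest p had non-overlapping groups, 3 of 3 libraries against 3 of 3, and were 7 genes lower and 3 genes higher in stress. Pdha1, which encodes the E1 alpha subunit of pyruvate dehydrogenase (chromosome X, 160122219 to 160138430), was at 41.5 ± 5.99 CPM in stress and 81.8 ± 15.3 in control oocytes (SD, n = 3), a log2 fold change of -0.98 with an SE of 0.205. Chd2, a chromatin remodeller (chromosome 7, 73426652 to 73541746), was at 0.970 ± 0.356 against 3.33 ± 0.445 CPM, and Stra6l, a retinol transporter gene (chromosome 4, 45824293 to 45887010), at 27.4 ± 6.30 against 72.2 ± 23.0 CPM. Wfs1, the endoplasmic reticulum membrane protein wolframin (chromosome 5, 36966104 to 36988982), was at 121 ± 5.65 CPM in stress and 65.6 ± 14.1 in control. Ica1l was at 17.5 ± 2.65 against 7.13 ± 1.79 CPM, and Slco4c1, an organic anion transporter, at 1.67 ± 0.440 against 0.373 ± 0.0351 CPM. The lower genes also included Plekhb1 (2.15 ± 0.843 against 8.61 ± 2.70 CPM), Rufy2 (4.33 ± 1.11 against 10.2 ± 2.04), Rmnd1, a factor of mitochondrial translation (0.358 ± 0.148 against 1.78 ± 0.425), and the bicarbonate transporter Slc4a10 (2.64 ± 0.550 against 8.87 ± 3.57).

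None of these genes passed the edgeR test over all genes in the fit of all 9 libraries. There 0 genes were called, the smallest adjusted p was 1.00, and 373 genes had an unadjusted p under 0.05 (153 higher, 220 lower), where 694 were expected by chance. Groups did not overlap in 7.88% of genes, where chance gives 10%. The DESeq2 Wald test called 22 genes (5 higher, 17 lower), including all 10 named here, and 9 of the 22 had a value of 0 in at least 2 of the 6 libraries. With the replicate number as a block in a fit of the control and stress libraries, 1 gene was called, Mettl7a1, with a log2 fold change of -2.63 (20.4 ± 9.57 CPM in control and 3.18 ± 1.05 in stress). Without control 3, 2 genes were called, Kcng2 and Vwa5a, both higher in stress, with log2 fold changes of 13.28 and 9.62. That fit rests on control 1 and control 2 for the control group. Without the 4 libraries of highest marker score, 148 genes were called (78 higher, 70 lower) with 2 residual degrees of freedom, while the other 2 ways of splitting the same 4 control and stress libraries gave 0 and 1 genes. That fit assumes that the lone KYZY 1 varies like the other groups. Its calls included Pdha1, Plekhb1, Stra6l, Rmnd1, Slc4a10 and Ica1l. Only 3 such splits exist, so no share under 0.05 can be reached. The split that gave 0 genes keeps same-numbered libraries together. Pdha1 passed when p was adjusted over the list alone, the glycolysis and tricarboxylic acid cycle list, with an adjusted p of 0.0305. That value is not adjusted over the 30 lists tested this way in each comparison. Only Pdha1 passed in any list, here and in KYZY against stress, which uses the same stress libraries.

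Nuclear-encoded subunits of oxidative phosphorylation, which build the respiratory chain and ATP synthase, were lower in stress than in control: 68 of 81 members were lower, with a median log2 fold change of -0.39 (camera, adjusted p = 0.000169, and adjusted p = 0.979 with an estimated correlation). Abundant members such as Atp5b (480 ± 90.7 CPM in stress, 480 ± 90.4 in control) and Uqcrc2 (281 ± 28.8 and 262 ± 50.7 CPM) had means within 1 SD of each other. Meiosis and spindle genes were higher, 43 of 51 members with a median of 0.15 (adjusted p = 0.00972, and adjusted p = 0.979 with an estimated correlation); Ccnb1, the cyclin of maturation-promoting factor, was at 4801 ± 1419 CPM in stress and 4486 ± 860 in control. Maternal mRNA translation and decay genes were higher in 35 of 47 members with a median of 0.11 (adjusted p = 0.0435, and adjusted p = 0.979 with an estimated correlation), with Btg4, a factor of maternal mRNA decay, at 4466 ± 2959 and 4251 ± 1413 CPM. No member of these lists passed over all genes or adjusted over the list alone. The mean cumulus marker score was 1.73 ± 0.509 in stress and 1.81 ± 0.790 in control. Other cell markers were lower in stress along with oxidative phosphorylation: 14 of 16 for oviduct epithelium (median -0.83) and 17 of 23 for stroma and endothelium (median -0.62), neither of them called in the fit of all 9 libraries. Oviduct markers were called lower without control 1 (median -1.52, adjusted p = 0.00364) or stress 2 (-1.47, 0.00784), and stroma and endothelium markers without control 1 (-1.12, 0.0289). Without control 3 their medians were 0.22 and 0.67, neither of them called. Control 3 had the highest oviduct, stroma and oxidative phosphorylation scores of these 6 libraries, 2.16, 2.24 and 3.18.

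Leaving out single libraries ended these list calls. Without control 3, the library of highest marker score in its group, the median of the oxidative phosphorylation list was 0.09 (adjusted p = 0.884), and without the 4 libraries of highest score it was -0.01 (adjusted p = 0.920); voom gave -0.19 (0.123). Over all alternatives its adjusted p ranged from 1.55e-08 to 0.920. The meiosis and spindle list was not called without control 2 (adjusted p = 0.454), control 3 (0.197) or stress 3 (0.923), where its median was -0.08. It was not called without the 4 libraries (0.934) or with voom (0.713), over a range of 1.2e-05 to 0.934. Its median was 0.06 without control 2 and 0.24 without stress 1. The maternal mRNA list was not called without control 2 (0.206), control 3 (0.610), stress 3 (0.632) or KYZY 3 (0.0558). It was not called either with the replicate block in control and stress (0.0640), the stricter filter (0.0520), only these groups (0.0636), the marker covariate (0.0816), voom (0.683) or without the 4 libraries (0.951), over a range of 0.000234 to 0.951. Its median was 0.06 without control 2, 0.02 without stress 3 and 0.19 without stress 2.

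The other 27 lists did not pass in stress against control in the fit of all 9 libraries. Cytosolic ribosomal protein genes had a median of -0.64 with 77 of 87 members lower, and cohesin genes a median of 0.16 with 22 of 30 higher, both at an adjusted p of 0.0746. The ribosomal list was called lower without control 1 (median -1.01, adjusted p = 3.87e-05), control 2 (-1.01, 0.000124), stress 2 (-0.98, 0.000127) or KYZY 1 (-0.64, 0.0344) and with DESeq2 (0.00102), but higher without control 3 (0.43, 0.0253). The cohesin list was called higher with the replicate block in control and stress (0.0344), with DESeq2 (0.0214) and without control 3 (0.28, 0.0158), stress 1 (0.22, 0.0487) or stress 2 (0.17, 0.00134). Antioxidant genes (-0.39, adjusted p = 0.114), mitochondrial ribosomal proteins (-0.19, 0.114), proteasome subunits (-0.20, 0.126) and DNA methylation and histone modification genes (0.09, 0.126) came next. The antioxidant, mitochondrial ribosomal and proteasome lists were called lower with DESeq2 (0.0143, 0.0214 and 0.0481), the stricter filter (0.0430 each) and counts divided by 4 (0.0490 each). Antioxidant (-0.41, 0.0457) and proteasome genes (-0.31, 0.0465) were also called without control 2, and DNA methylation and histone modification genes, higher, without control 1 (0.05, 0.0272). Medians were 0.06 for maternal-effect genes, 0.06 for egg activation, 0.01 for mitochondrial dynamics, -0.05 for glycolysis and the tricarboxylic acid cycle, -0.10 for lipid metabolism, -0.07 for heat shock, -0.02 for endoplasmic reticulum stress, -0.08 for apoptosis, and 0.03 for DNA repair. They were 0.00 for autophagy and lysosome, 0.04 for PI3K, mTOR and insulin signalling, and 0.02 for the spliceosome. They were -0.03 for translation factors, 0.10 for zygotic genome activation and -0.09 for imprinted genes. The adjusted p of these lists was 0.201 to 0.952. Glucocorticoid response genes had a median of -0.19 and inflammation and interferon genes one of -0.16, with Fkbp5, a glucocorticoid-induced chaperone, at 733 ± 14.2 CPM in stress and 597 ± 122 in control. Maternal-effect genes were called higher without control 1 (0.21, 0.000117) or stress 2 (0.16, 0.0204). The median was -0.19 for blood and immune cell markers and 0.01 for cumulus and granulosa markers, a value that single libraries decided: it was 2.85 without control 3 (0.0158, called higher) and -2.09 without stress 3, and was called higher with the marker covariate (0.65, 0.0353). Of these 27 lists, 10 were called under at least 1 alternative, and the median of 22 changed sign with some 1 library left out. In 10 of the 30 lists, none of them called, the median, the mean and the test differed in sign.

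**Figure D2:**
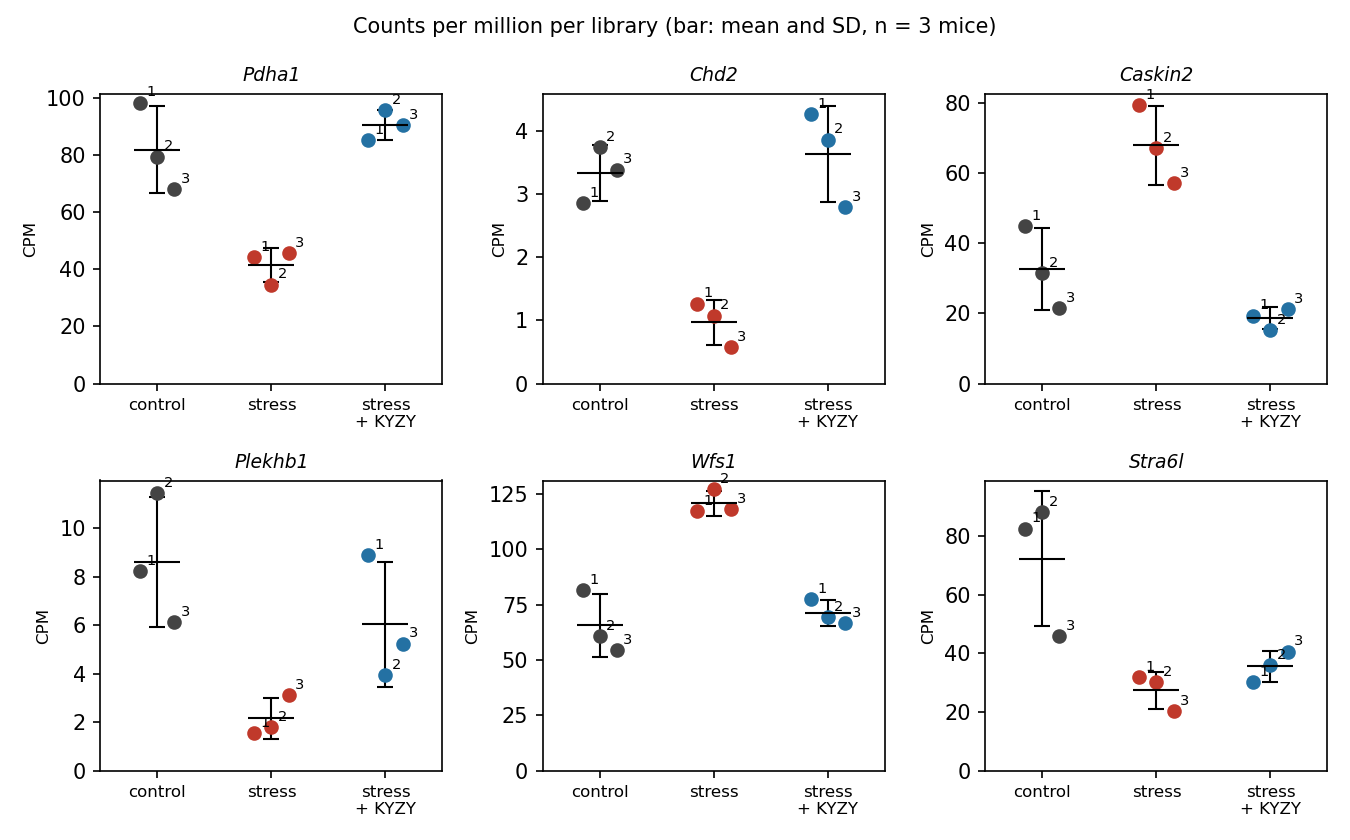
CPM of Pdha1, Chd2, Caskin2, Plekhb1, Wfs1 and Stra6l in each of the 9 libraries by group; points are mice numbered by replicate, and bars give the mean and SD of 3 mice. Pdha1 stands at 41.5 ± 5.99 CPM in stress, below 81.8 ± 15.3 in control and 90.4 ± 5.25 in KYZY. No gene in the plot passed the edgeR test over all genes in the fit of all 9 libraries.

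The comparison of KYZY with stress asked which transcripts differ when stressed mice are given the recipe. Caskin2, a scaffold protein gene (chromosome 11, 115798987 to 115813658), had the smallest p of all genes: 18.7 ± 3.07 CPM in KYZY and 67.9 ± 11.2 in stress (SD, n = 3), a log2 fold change of -1.86 with an SE of 0.282 and an adjusted p of 0.729. Pdha1 was at 90.4 ± 5.25 against 41.5 ± 5.99 CPM, a log2 fold change of 1.12 with an SE of 0.205, and Chd2 at 3.64 ± 0.759 against 0.970 ± 0.356 CPM, each with an adjusted p of 0.935. Also higher in KYZY were Birc2, an inhibitor of apoptosis (chromosome 9, 7818226 to 7837131; 7.31 ± 1.44 against 2.45 ± 1.20 CPM), the metalloprotease Adam8 (8.22 ± 1.67 against 3.84 ± 0.256) and the poly(A)-binding protein gene Zc3h14 (26.7 ± 6.67 against 12.6 ± 1.11). The same held for the proton pump subunit Atp6v0e2 (3.26 ± 0.893 against 1.00 ± 0.164) and the carbonic anhydrase Car9 (43.9 ± 7.23 against 25.7 ± 1.39). Steap4, a metalloreductase, was at 7.64 ± 0.833 against 19.01 ± 7.14 CPM, and the predicted gene Gm11758 at 0.0105 ± 0.0182, under the floor, against 0.884 ± 0.449 CPM.

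With edgeR 0 genes were called, although 553 had an unadjusted p under 0.05 (299 higher, 254 lower; 694 expected by chance). Groups did not overlap in 9.19% of genes, where chance gives 10%. DESeq2 called 13 genes (10 higher, 3 lower), of which 6 are among the 10 named and 7 had a value of 0 in at least 2 of the 6 libraries. Prr18 was the 1 gene called in a fit of only these groups and in the fit without control 3 (0.217 ± 0.0474 CPM in KYZY, 15.1 ± 7.22 in stress), and Caskin2 the 1 gene called by voom with library weights (adjusted p = 0.0460, over all alternatives 5.29e-06 to 1.00). With the marker score as a covariate, 5 genes were called, all lower after this adjustment, namely Inhba, Sfrp2, Skil, Slc16a3 and Tnfaip6. Of these, Inhba and Tnfaip6 are themselves in the score. Their adjusted log2 fold changes were -8.56 and -11.2, but their measured levels were not lower throughout. Tnfaip6 was at 0, 16.5 and 10.4 CPM in KYZY 1, 2 and 3 and at 0, 0 and 5.14 in stress 1, 2 and 3. Inhba was at 0, 3.39 and 3.55 CPM against 0, 0.0872 and 4.24 in the same order. Without the 4 libraries of highest marker score, 115 genes were called (49 higher, 66 lower), with KYZY 1 alone in its group and 2 residual degrees of freedom. Pdha1 again passed adjusted over the list alone, with an adjusted p of 0.0110, again without adjustment over the lists. The KYZY libraries have another sequencing description, and the labels name no stressed group given a vehicle for 4 weeks, so these cannot be separated from the recipe.

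Cytosolic ribosomal protein genes were higher in KYZY than in stress in 80 of 87 members, with a median log2 fold change of 1.45 (camera, adjusted p = 1.13e-16, and adjusted p = 0.632 with an estimated correlation). Oxidative phosphorylation subunits were higher in 68 of 81 members with a median of 0.69 (adjusted p = 1.82e-09), and antioxidant genes in 35 of 46 with a median of 0.62 (adjusted p = 0.00249), both at an adjusted p = 0.632 with an estimated correlation. Markers of cumulus and granulosa cells were higher in 32 of 34 members, with a median of 1.80 (adjusted p = 2.97e-05, and adjusted p = 0.632 with an estimated correlation). Among the members of highest expression, Rpl4 was at 379 ± 20.02 against 312 ± 31.05 CPM, and Rpl17 at 188 ± 48.9 against 228 ± 26.6. Atp5b was at 536 ± 96.0 against 480 ± 90.7, and the peroxiredoxin Prdx1 at 1675 ± 135 against 1476 ± 507. Chosen after their values were seen, Cox7b, a cytochrome c oxidase subunit, was at 2.67 ± 1.49 against 0.783 ± 0.403 CPM, and Cox6b1, another subunit, at 12.2 ± 5.77 against 6.10 ± 1.22 CPM. The glutathione peroxidase Gpx1, chosen likewise, was at 8.52 ± 6.64 against 2.60 ± 0.578 CPM.

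These list differences moved with the marker score only in part. That score was 2.74 ± 1.07 in KYZY and 1.73 ± 0.509 in stress. The ribosomal protein score was 2.94, 4.46 and 5.13 in KYZY 1, 2 and 3 and 2.53, 3.66 and 3.36 in stress 1, 2 and 3. The oxidative phosphorylation score was 2.40, 2.88 and 3.36 against 2.39, 2.49 and 2.44. Stress 3 had a higher marker score than stress 2, 2.30 against 1.59, but lower scores of both lists and the same antioxidant score, 2.78. KYZY 3, highest in both lists, also had the highest stroma and oviduct marker scores of these libraries, 2.52 and 2.28. With the marker score as a covariate, the median was -0.15 for the ribosomal list (adjusted p = 0.946), 0.00 for oxidative phosphorylation (0.564), -0.15 for antioxidant genes (0.613) and -1.11 for the markers that make up the score (0.00426, lower). Without the 4 libraries of highest marker score, the medians were -0.38, -0.11, -0.19 and 0.01 in the same order, and none of these lists was called. The antioxidant list was also not called without KYZY 3 (adjusted p = 0.258). Without KYZY 3 the medians were 0.87 for ribosomal proteins, 0.31 for oxidative phosphorylation and 0.40 for antioxidant genes. The antioxidant median was 0.97 without KYZY 1, and the marker median was 4.12 without stress 3. Over all alternatives the adjusted p ranged from 9.29e-34 to 0.946 for ribosomal proteins, 4.17e-12 to 0.903 for oxidative phosphorylation, 5.72e-05 to 0.738 for antioxidant genes and 3.6e-09 to 0.565 for the markers.

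Genes of zygotic genome activation were higher in KYZY than in stress in 13 of 14 members (median 0.69, adjusted p = 0.0226) and apoptosis genes in 28 of 44 (median 0.22, adjusted p = 0.0226), while DNA repair genes were lower in 48 of 67 (median -0.20, adjusted p = 0.00763). All 3 lists had an adjusted p = 0.509 with an estimated correlation, and no member passed over all genes or adjusted over the list alone. Examples were Sp110 (481 ± 171 against 460 ± 58.1 CPM), the oocyte-expressed Bcl2l10 (6802 ± 1340 against 6441 ± 959 CPM) and the checkpoint kinase Chek1 (823 ± 206 against 759 ± 133 CPM). Chosen after its values were seen, the ubiquitin ligase Rnf8 was at 71.5 ± 11.2 against 110 ± 32.9 CPM. The repair list was not called without KYZY 3 (adjusted p = 0.146), and the apoptosis list without stress 1 (0.0596) or KYZY 3 (0.0946). The genome activation list was not called without any 1 of control 1, 2 or 3, stress 1 or 3, or KYZY 1 or 2, at an adjusted p of 0.0551 to 0.483. The repair and apoptosis lists were also not called with the marker covariate (adjusted p = 0.613 and 0.180), and none of the 3 was called without the 4 libraries of highest score (0.903, 0.320 and, for genome activation, 0.188). Apoptosis genes were not called with DESeq2 (0.0543), the stricter filter (0.249), only these groups (0.132), counts divided by 4 (0.177) or voom (0.0996). Genome activation genes were not called with DESeq2 (0.0725), no filter (0.263), Rn45s left out (0.0878) or voom (0.231). Without KYZY 3 the repair median was -0.10. The apoptosis median was 0.34 without control 2 or KYZY 2 and 0.35 without stress 1. The genome activation median ranged from 0.31 without KYZY 1 to 1.04 without stress 2, with 0.33 without KYZY 2, 0.43 without control 1 and 0.46 without control 2. Over all alternatives the adjusted p ranged from 0.00379 to 0.903 for repair, 0.0207 to 0.320 for apoptosis and 0.00398 to 0.483 for genome activation genes.

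The other 23 lists did not pass in KYZY against stress in the fit of all 9 libraries. Medians were 0.03 for maternal-effect genes, -0.08 for meiosis and spindle, 0.07 for cohesin, -0.03 for egg activation, -0.10 for maternal mRNA translation and decay, -0.15 for DNA methylation and histone modification (adjusted p = 0.0851), and 0.18 for translation factors (adjusted p = 0.0924). They were 0.50 for glucocorticoid response (adjusted p = 0.109), 0.15 for the proteasome (adjusted p = 0.120) and 0.24 for glycolysis and the tricarboxylic acid cycle. Maternal-effect genes were called higher with the marker covariate (0.13, adjusted p = 0.0256), without stress 3 (0.12, 0.0386) and without the 4 libraries of highest score (0.57, 1.2e-09), where KYZY 1 stands alone, but lower without KYZY 1 (-0.21, 0.0143). Meiosis and spindle genes were called lower without stress 1 (-0.14, 0.0312), stress 2 (-0.15, 0.0115) or KYZY 1 (-0.17, 0.0269) and higher without the 4 libraries (0.21, 0.0140). DNA methylation and histone modification genes were called lower without stress 2 (-0.06, 0.0428), KYZY 1 (-0.25, 0.0494) or KYZY 2 (-0.12, 0.0272) and with no filter (0.0494), and maternal mRNA genes lower without stress 2 (-0.09, 0.0378). Translation factors were called higher without stress 3 (0.31, 0.0386), with the stricter filter (0.0358) and with voom (0.0338), and proteasome genes without KYZY 1 (0.24, 0.0318), with the stricter filter (0.0358) and with voom (0.0156). Glucocorticoid response genes were called higher without KYZY 1 (0.60, 0.0269) and heat shock genes without stress 3 (0.33, 0.0386). Marker medians were 1.05 for oviduct epithelium, 1.25 for blood and immune cells and 1.42 for stroma and endothelium, at an adjusted p of 0.248 to 0.570; Lyz2, a macrophage gene, reached 58.1 CPM in KYZY 2. Blood and immune markers were called higher without stress 2 (3.09, 0.0310) or KYZY 1 (2.09, 0.0120) and lower without the 4 libraries (-5.92, 0.0140), and oviduct markers higher without stress 2 (2.44, 0.0428) or KYZY 2 (2.11, 0.0412). The stroma and endothelium median was -0.64 without KYZY 3, not called. Of these 23 lists, 10 were called under at least 1 alternative, 3 of them in both directions, and the median of 11 changed sign with some 1 library left out. In 4 of the 30 lists, none of them called, the median, the mean and the test differed in sign.

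**Figure D3:**
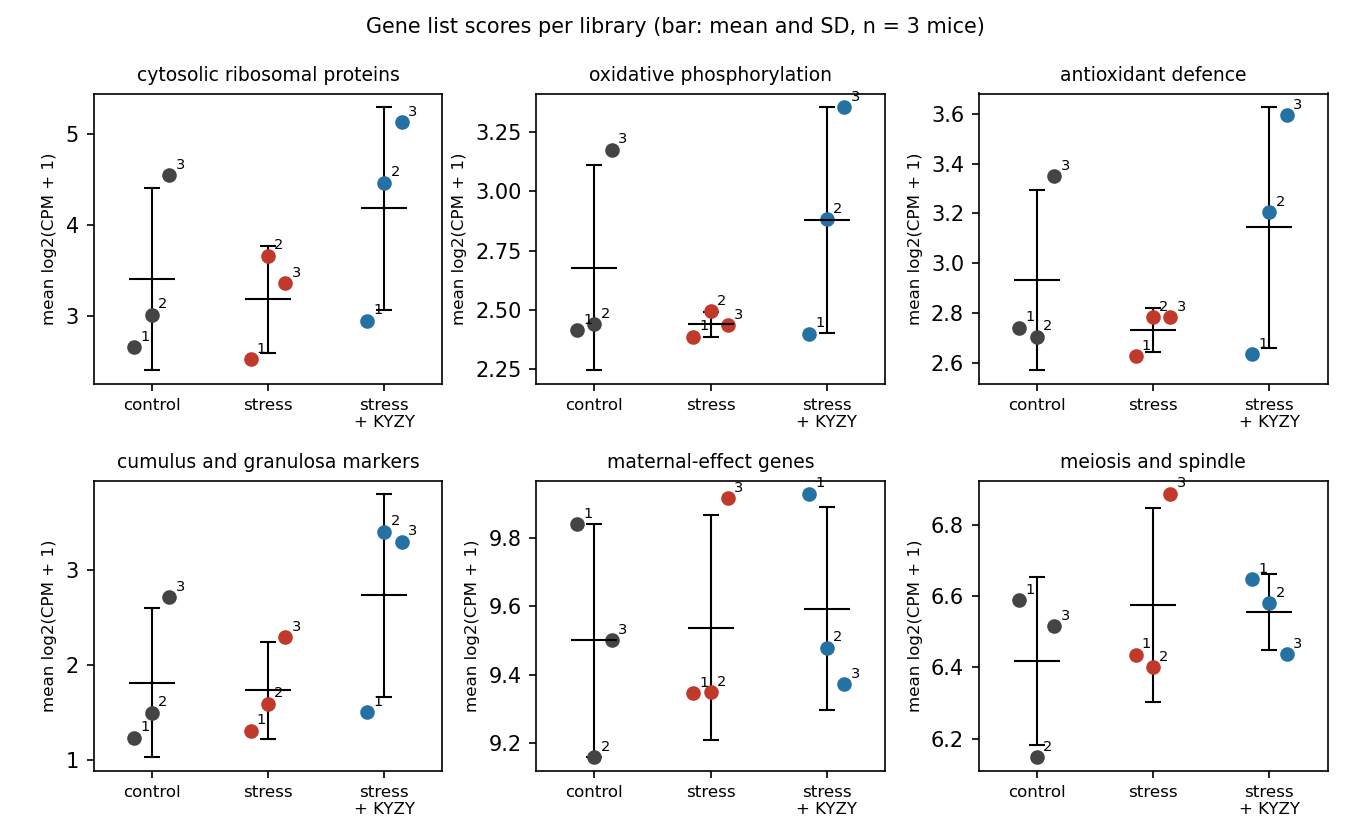
Score of 6 gene lists in each library, the mean log2(CPM + 1) of the members tested, by group; points are mice numbered by replicate, and bars give the mean and SD of 3 mice. KYZY 2 and KYZY 3 have ribosomal protein scores of 4.46 and 5.13 and KYZY 1 has 2.94, within the range of 2.53 to 3.66 of the stress libraries.

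The comparison of KYZY with control asked whether oocytes of treated stressed mice differ from those of untreated mice. The genes with the smallest p included Anapc16, a subunit of the anaphase-promoting complex (chromosome 10, 59987409 to 60003135), at 35.9 ± 7.14 CPM in KYZY and 84.9 ± 13.8 in control (SD, n = 3), with a log2 fold change of -1.24 and an SE of 0.326. Tet1, a 5-methylcytosine dioxygenase (chromosome 10, 62804570 to 62887469), was at 0.397 ± 0.0848 against 1.43 ± 0.283 CPM, and Dnajb4, a heat shock co-chaperone, at 128 ± 23.9 against 334 ± 80.9 CPM. Stra6l was at 35.6 ± 5.23 against 72.2 ± 23.0 CPM, Pdpn, a mucin-like membrane glycoprotein, at 16.6 ± 4.86 against 33.0 ± 8.22 CPM, the intraflagellar transport gene Ift22 at 2.69 ± 0.281 against 5.21 ± 1.21 CPM and 9230110C19Rik, without coordinates in the annotation, at 7.89 ± 2.38 against 15.6 ± 3.82 CPM. Gm11758 was at 0.0105 ± 0.0182 against 0.834 ± 0.196 CPM. Dgka, a diacylglycerol kinase, was at 0 in all controls and at 0.308 ± 0.175 CPM in KYZY. Its group mean was at least 1.97-fold higher against a group floor of 0.156 CPM, but KYZY 3, at 0.122 CPM, was under its own floor of 0.245. Calhm2 was at 0 in all KYZY libraries and at 0.369 ± 0.0402 CPM in control, at least 1.81-fold lower against a group floor of 0.204 CPM. Pdha1 (90.4 ± 5.25 against 81.8 ± 15.3 CPM) and Chd2 (3.64 ± 0.759 against 3.33 ± 0.445 CPM) differed by less than the spread between control mice.

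With edgeR 0 genes were called, the smallest adjusted p was 0.996, and 380 genes had an unadjusted p under 0.05 (121 higher, 259 lower; 694 expected by chance). Groups did not overlap in 7.23% of genes, where chance gives 10%. DESeq2 called 1 gene, Gm11758 (adjusted p = 0.0143, over all alternatives up to 1.00). Without control 3, 3 genes were called: Kcng2 and Vwa5a, higher in KYZY with log2 fold changes of 13.27 and 10.2, and Prr18, lower at -6.54. Kcng2 and Vwa5a were also called without control 3 in stress against control, which uses the same controls, so these calls are not independent. Without the 4 libraries of highest marker score, 119 genes were called (52 higher, 67 lower), with KYZY 1 alone in its group.

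Cytosolic ribosomal protein genes were higher in KYZY than in control in 79 of 87 members with a median of 0.85 (adjusted p = 5.9e-11), and cumulus and granulosa markers in 30 of 34 with a median of 1.82 (adjusted p = 4.46e-07), both at an adjusted p = 0.873 with an estimated correlation. The marker median was 1.74 with the 1 marker whose group was at 0 set at its bound. Genome activation genes were higher in 9 of 14 (median 0.55, adjusted p = 0.0141), oxidative phosphorylation subunits in 57 of 81 (0.23, 0.0405), translation factors in 41 of 56 (0.18, 0.0432) and cohesin genes in 23 of 30 (0.18, 0.0432), and DNA repair genes were lower in 44 of 67 (-0.15, 0.0381). These 5 lists also had an adjusted p = 0.873 with an estimated correlation, and no member of the 7 lists passed over all genes or adjusted over the list alone. Eef1a1, the elongation factor, was at 1282 ± 167 CPM in KYZY and 861 ± 241 in control, and Smc4, a condensin subunit, at 1387 ± 433 against 816 ± 674 CPM. The marker score was 2.74 ± 1.07 in KYZY and 1.81 ± 0.790 in control. With this score as a covariate, the ribosomal median was -0.23 (adjusted p = 0.365), the marker median -0.41 (0.302), the translation factor median -0.01 (0.281) and the oxidative phosphorylation median -0.23 (0.0349, lower). The cohesin and repair lists were not called with it either (0.281 and 0.727). Without the 4 libraries of highest score, the ribosomal, marker, oxidative phosphorylation, translation factor and repair lists were not called (adjusted p = 0.560, 0.566, 0.957, 0.311 and 0.745).

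Leaving out 1 library ended the calls of 5 lists. The ribosomal median was 0.57 without control 1, 1.97 without control 3, 1.28 without KYZY 1 and 0.22 without KYZY 3, with an adjusted p of 2.85e-25 to 0.560 over all alternatives, and the marker median was 5.70 without control 3, with 2.92e-11 to 0.566. The oxidative phosphorylation list was not called without control 1 (adjusted p = 0.317), control 2 (0.715), stress 3 (0.0535) or KYZY 3, where its median was -0.12 (0.671). It was not called with no filter (0.0853) or only these groups (0.0538), over a range of 2.8e-05 to 0.957. The median was 0.11 without control 1, 0.09 without control 2, 0.69 without control 3, 0.51 without KYZY 1 and 0.35 without KYZY 2. Cohesin genes were not called without control 2 (0.623), KYZY 1 (0.238) or KYZY 2 (0.117), nor with no filter (0.0665), over a range of 0.00771 to 0.623. Their median was 0.10 without control 2 and 0.37 without control 3. Genome activation genes were not called without control 2 (0.263), KYZY 1 (0.229) or KYZY 2 (0.0776). They were not called with the stricter filter (0.0719), only these groups (0.0517) or voom (0.311), over a range of 0.000307 to 0.311. Their median was 0.35 without control 1, 0.25 without control 2, 1.59 without control 3 and 0.35 without KYZY 3. DNA repair genes were not called without control 1 (0.180), control 2 (0.157), KYZY 2 (0.0776) or KYZY 3 (0.396), nor with the stricter filter (0.0631), over a range of 0.00615 to 0.745. Their median was -0.08 without control 2 and -0.09 without KYZY 3. Translation factors were not called without control 2 (0.623), control 3 (0.0532), stress 3 (0.0515), KYZY 1 (0.109) or KYZY 2 (0.0776), nor with no filter (0.0895) or voom (0.0609), over a range of 0.00243 to 0.623. Their median was 0.07 without control 2, 0.31 without control 3 and 0.10 without KYZY 1.

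Among the 23 lists that did not pass in the fit of all 9 libraries, the median was 0.31 for antioxidant genes (adjusted p = 0.264), 0.27 for glucocorticoid response genes (0.197) and 0.12 for maternal-effect genes (0.523). Blood and immune markers had a median of 1.62 with 10 of 14 higher (0.329), stroma and endothelium markers one of 0.31 with 19 of 23 higher (0.525), and oviduct epithelium markers one of 0.05 (0.796). Maternal-effect genes were called higher without control 1 (0.29, 0.000319) or KYZY 3 (0.24, 0.0194), with the marker covariate (0.18, 0.00155) and without the 4 libraries of highest score (0.40, 0.000299), where KYZY 1 stands alone. Meiosis and spindle genes were called higher without control 1 (0.13, 0.00481) or KYZY 3 (0.13, 0.0194) and without the 4 libraries (0.23, 0.00771), and maternal mRNA genes without control 1 (0.09, 0.0380) or KYZY 3 (0.14, 0.0290). Antioxidant (0.54, 0.00908) and glucocorticoid response genes (0.58, 0.0228) were called higher without KYZY 1. Blood and immune markers were called higher without stress 1 (2.16, 0.0460), stress 2 (2.16, 0.0426) or KYZY 1 (2.44, 0.000993), oviduct markers lower without KYZY 3 (-1.40, 0.0377), and stroma and endothelium markers lower with the covariate (-1.05, 0.0480). Of these 23 lists, 8 were called under at least 1 alternative, and the median of 15 changed sign with some 1 library left out. In 7 of the 30 lists, none of them called, the median, the mean and the test differed in sign.

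Whether genes that differ under stress differ the other way with KYZY was measured by correlating the log2 fold changes of stress against control and of KYZY against stress across 13890 genes, which are not independent replicates. Pearson's r was -0.646 and Spearman's rho -0.487, with a covariance of -0.675. Both comparisons use the 3 stress libraries, which alone gives a negative value: 20 simulations of unchanged groups that share them gave a mean r of -0.496, from -0.526 to -0.469, and a mean covariance of -0.459, from -0.509 to -0.411. The simulated genes varied independently, while real libraries vary along shared components, so the simulated ranges set no bound. Genes with an unadjusted p under 0.05 in both comparisons numbered 126, all with opposite signs, where the simulations gave a mean of 136. These counts cannot be compared directly. Only 373 and 553 genes had an unadjusted p under 0.05 in the 2 comparisons, where 694 were expected by chance. Pdha1 and Chd2 were among the 10 smallest p of both comparisons. With the 3 stress libraries divided between the comparisons, so that none was shared, and fold changes taken from group means of log2 CPM, the 6 possible divisions gave r of -0.311 to 0.340 with a mean of -0.0023. On the same scale, r was -0.426 with the libraries shared. Without control 3, r was 0.0371.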

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

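The alternatives that divide counts by 4, leave out Rn45s, use the marker score, leave out its 4 highest libraries, use voom weights or block within control and stress were chosen only after the data were seen. Genes called, 0 in each comparison with edgeR, numbered 22, 13 and 1 with DESeq2 (stress against control, KYZY against stress, KYZY against control), 148, 115 and 119 without the 4 libraries of highest marker score, and 5 (KYZY against stress) with the score as covariate. KYZY against stress gave 1 gene with only its groups fitted and 1 with voom, and stress against control gave 1 with the replicate block in control and stress. Leaving out 1 library gave 0 to 2, 0 to 1 and 0 to 3 genes, the highest values all without control 3; the other settings gave 0. DESeq2 estimates of Adcyap1, C1s1, Flrt2, Nfam1 and Rhox8 exceeded 20 on the log2 scale in 2 comparisons. Fewer libraries and 2 residual degrees of freedom are part of the fit without 4 libraries; for all other changes the cause was not tested.

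Lists called, 3 in stress against control, numbered 8 with DESeq2, 5 with at least 50 counts, 6 with counts divided by 4, 0 without the 4 libraries, 0 with voom, and 1 (without stress 3) to 8 (without control 1) with 1 library left out, with 7 without stress 2. In KYZY against stress, 7 became 3 with the covariate, 3 without the 4 libraries, and 4 (without KYZY 3) to 12 (without stress 2 or KYZY 1) with 1 library left out; in KYZY against control, 7 became 4 with no filter, 4 with the covariate, 4 without the 4 libraries, and 2 (without control 2) to 9 (without KYZY 3) with 1 library left out, with 3 without KYZY 2. With the covariate, medians in KYZY against stress were -0.15 for antioxidant genes, -0.15 for ribosomal proteins and -1.11 for cumulus markers, and in KYZY against control -0.41 for cumulus markers, -0.23 for oxidative phosphorylation, -0.23 for ribosomal proteins and -0.0068 for translation factors. Without the 4 libraries, they were -0.19 for antioxidant genes, -0.11 for oxidative phosphorylation and -0.38 for ribosomal proteins in KYZY against stress, -0.0077 for oxidative phosphorylation in KYZY against control and -0.011 for maternal mRNA genes in stress against control. With 1 library left out, the median ranged from -0.081 to 0.24 for meiosis genes and from -0.57 to 0.086 for oxidative phosphorylation in stress against control, and from -0.12 to 0.69 for oxidative phosphorylation in KYZY against control. For the 17 lists called, over all settings, 269 results kept direction and side of the threshold, 76 were no longer called and 15 changed direction. The 73 lists not called gained 73 calls, 46 of them with 1 library left out, and 4 of these lists were called in both directions. Named genes kept their direction under every setting run, but they were picked by the smallest p in these same libraries, which makes that likely. The threshold was passed by 29 of these gene results, all of them with DESeq2, with voom or without the 4 libraries.

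The correlation of fold changes ranged from -0.837 (without stress 3) to 0.0371 (without control 3), and was -0.390 without the 4 libraries. Replicate numbers did not pair the KYZY libraries: same-numbered deviations correlated at 0.506, -0.144 and 0.559 with control and at 0.402, -0.146 and 0.171 with stress. The replicate block over 9 libraries gave 0, 0 and 0 genes, 4, 7 and 6 lists and a correlation of -0.512, called ribosomal proteins, lower, in stress against control (adjusted p = 0.0388), and ended the call of genome activation genes in KYZY against control (0.0613). The block in control and stress changed no call other than those of the maternal mRNA list, the cohesin list and Mettl7a1. A pseudocount of 0.1 was not run because the tables hold counts, and leaving out mitochondrial genes was not run because the tables hold 0 of them. At this depth and spread, 2-fold changes were recovered in 2% to 4% of simulated genes.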

Other observations

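The tests of the first principal component against marker genes and against the sequencing description, and of the ribosomal list against the sequencing description, were chosen only after the result was seen, and the division of the stress libraries was added after the correlation with shared libraries was seen.

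Further enzymes of mitochondrial carbon metabolism and meiotic genes, chosen after their values were seen, are given here. Ogdh, the E1 subunit of the 2-oxoglutarate dehydrogenase complex, was at 78.9 ± 1.71 CPM in stress, 48.8 ± 9.79 in control and 46.7 ± 10.4 in KYZY (SD, n = 3), and the pyruvate dehydrogenase kinase Pdk1 at 15.3 ± 1.22, 13.8 ± 5.76 and 7.58 ± 1.43 CPM. Aurkc, the meiotic Aurora kinase, was at 79.4 ± 15.5 CPM in control, 165 ± 84.0 in stress and 193 ± 88.8 in KYZY, and Fmn2, an actin nucleator of spindle positioning, at 44.4 ± 15.7, 67.6 ± 8.19 and 65.6 ± 13.8 CPM. None of Ogdh, Pdk1, Aurkc and Fmn2 passed over all genes with edgeR in any comparison in the fit of all 9 libraries. Aurkc passed without the 4 libraries of highest marker score in stress against control (log2 fold change 1.60, adjusted p = 0.0104), a fit of 2 libraries in each of these groups.

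Control 3, stress 3, KYZY 2 and KYZY 3 stood apart on the first principal component and came from all 3 groups. Library size is argued against as the whole source. The gap to the other 5 libraries was 57.6 after every library was thinned to 46324094 counts and 59.5 before. Thinning drew single units, while 1 read pair appeared to be worth about 4, so it does not settle genes with few read pairs. Control 3 and stress 3 had totals of 72154974 and 80606254, within the range of the other 5 libraries, 68826061 to 106990821. KYZY 2 and KYZY 3, at 67892072 and 46324094, lay below that range. The other sequencing description of the KYZY libraries is argued against as the whole source, since KYZY 1 lay at -63.25. Control 3 and stress 3, which have the description of the other groups, lay above it. RNA of cumulus cells left by the hyaluronidase step may account for part of it. Of 34 tested cumulus and granulosa markers, 18 (52.9%) were higher in each of the 4 libraries than in each of the other 5. The same held for 9.94% of all genes and 2 of 41 maternal-effect genes. Chance gives 0.794% only for 4 libraries fixed in advance, while these were picked from the same data, so that value decides nothing. Some markers, such as Tnfaip6, were at 0 in the other 5 and passed the filter only through these 4. Blood and immune markers (4 of 14, 28.6%), stroma and endothelium markers (6 of 23, 26.1%) and oviduct markers (2 of 16, 12.5%) were also above the share of all genes. RNA of other cells therefore stays open. Of the 41 listed markers, 7 had a median above 5 CPM in the 5 other libraries and 2 are in another list; Cyp11a1 was at 14.7 CPM in stress 3 and 165 or more in the other 3, and Star was at 0.373 in stress 3 and 4.86 in KYZY 2, so the mix of cells may differ. Differences in the oocytes themselves between mice stay open and were not tested.

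The higher level of cytosolic ribosomal protein genes in KYZY than in stress (camera, adjusted p = 0.632 with an estimated correlation) may come in part from carried-over cumulus RNA. The median log2 fold change of 1.45 became -0.15 with the marker score as a covariate. The covariate removes any effect that moves with the score, so an effect of the recipe on how many cumulus cells stay attached would give the same value and stays open. Against cumulus RNA alone, stress 3 had a higher marker score than stress 2 (2.30 against 1.59) but a lower ribosomal score (3.36 against 3.66). Markers of stroma and endothelium, blood and immune cells and oviduct epithelium had medians of 1.42, 1.25 and 1.05 in KYZY against stress. None of these lists was called (camera, adjusted p = 0.454, 0.248 and 0.570). Without KYZY 3 the stroma and oviduct medians were -0.64 and -0.13, so that library alone made them positive. The blood and immune median stayed above 0 with any 1 library left out, at 0.39 or more. RNA of these cells therefore stays open too. A difference in sequencing cannot be told apart from the recipe, because all 3 KYZY libraries have another sequencing description than the rest and whether they were a separate run is not stated; KYZY 1 had a list score of 2.944, between those of the stress libraries, but a single library excludes nothing.

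The opposite fold changes of stress against control and KYZY against stress may come from the shared stress libraries and from the spread between mice. The correlation of -0.646 lay below the lowest simulated value of -0.5262, a result set in advance as evidence against the shared libraries alone; that bound was wrong because the simulation treats genes as independent, while real libraries vary along shared components. With the stress libraries divided so that none was shared, the mean correlation over 6 divisions was -0.0023 (-0.311 to 0.340), and 29 of 100 regroupings gave a mean as low, which is consistent with the shared libraries as the source of the negative value. Of 100 regroupings of the 9 libraries into groups of the same sizes, 30 gave a correlation as low, the lowest other at -0.9307 and the median at -0.529, so chance cannot be excluded. Neither the regroupings nor the simulation took replicate numbers into account. A reversal by the recipe stays open, with Pdha1 and Chd2 as hypotheses for a repeat with separate stress groups.

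With 10 splits of 6 libraries, no share under 0.05 can be reached. In each comparison the real split gave 0 genes, so all 10 splits gave as many by construction, and that count decides nothing. The highest of the other splits gave 3 in stress against control and 4 in KYZY against stress. In KYZY against control, the split of control 1, control 2 and KYZY 1 against control 3, KYZY 2 and KYZY 3 gave 844. That points to a structure of the samples. This split separates the libraries as the first principal component does. The split of the same kind in KYZY against stress, stress 1, stress 2 and KYZY 1 against stress 3, KYZY 2 and KYZY 3, is the one that gave 4. Among the splits of control and stress libraries that part all 3 same-numbered pairs, the real one gave 0 genes and the others gave 3, 0 and 0; the remaining splits each keep a pair together and gave 0.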
